A study of Homo sapiens with 6 samples.

How the data were processed

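RNA sequencing was performed on 6 libraries of total RNA from the human lung adenocarcinoma line H1975: 3 of the parental line and 3 of its osimertinib-resistant derivative, H1975 OR. Per the labels' protocols, both were grown in the same serum-supplemented medium, RNA was extracted with Trizol, libraries were made with an mRNA library kit, and the resistant cells were kept in 1 µM osimertinib, an inhibitor of mutant EGFR. Groups were taken from the sample titles. The series design states 3 biological replicates per group. Resistance and the presence of the drug go together in this design, so no comparison here separates them. H1975 OR is the only resistant line, so changes tied to resistance cannot be told from other changes of this derivative. The labels give no batch or date.

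Reads were mapped to GRCh37, per the submitters' processing notes, which also name DESeq with no version and no role. The aligner, the quantification tool, the annotation release and whether strand was used are not given in the sources used here. The values the authors deposited are FPKM, fragments scaled to transcript length and to the mapped total, in a series table of 20356 gene IDs with 1 column per library. The authors' file of each library lists 57905 gene IDs and gives, per the file headers, coordinates, the mean coverage, the FPKM and the TPM. TPM in the deposited files was FPKM multiplied by 1 factor per library, from 2.25 to 2.38, and summed to 1000000. The series table and the library files were compared gene by gene, and between 1 and 4 genes per library differed by more than 0.00001 FPKM. Values of IDs on several rows of a library file were summed first. All columns of the series table were mapped to a sample.

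No counts of reads were used. The test fixed before the data were examined was a count model, with limma on FPKM named as the test if the files held only FPKM, and the latter was therefore used. Depth in reads is unknown. The deposited coverage of a gene divided by its FPKM had a highest ratio shared by 11.1% to 11.8% of genes above 1 FPKM, and this ratio was taken as an estimate of the mapped bases, in gigabases. No interval for counting error can be given, and an exact 0 may be a failed estimate: 8 genes were at 0 in some library and above 5 FPKM in another library of the same group. Genes at 0 in a whole group are therefore described as listed at 0, with the values of each library and no fold.

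Genes with a mean of at least 1 FPKM in either group were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, an intensity trend and robust moderation, two-sided, and Benjamini-Hochberg adjustment over all genes tested. Fold changes are resistant minus parental on the log2(FPKM + 1) scale, which understates the change of low genes. Adjusted p-values are those of limma unless a set test is named. For 40 gene lists fixed before the data were examined, with 787 of 789 members found by symbol or older symbol, the competitive set test camera was run with a preset inter-gene correlation of 0.01 on the 36 lists with at least 5 tested members, and adjusted over these lists. The same test was run on the tested genes of each chromosome with at least 50 of them. The rule for named genes was also fixed before. It takes the 7 largest changes in each direction among genes past an FDR of 0.05 that had a mean of at least 5 FPKM in the higher group, no overlap between the groups and a symbol that is neither a clone name nor a pseudogene. It adds EGFR, ERBB2, ERBB3, MET, AXL, DUSP6, CDH1 and VIM, 3 members of each list past the set test, and 2 members of other lists with at least 5 members past 0.05. Symbols that a spreadsheet had turned into dates, 29 in the table, were also passed over. The rule gave 92 genes, of which 1 is not reported here. Other genes named in the text were chosen after their values were seen. Gene types were taken by ID from GENCODE v29, which held 19511 of the 20356 IDs, and no coordinates were taken from it. All coordinates are GRCh37, 1-based, from the deposited files.

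The scripts were tested on simulated data with the parental means and a smoothed spread of the 12107 tested genes. For this comparison, 100% of genes changed by 0.5 and 100% of genes changed by 1 on the log2 scale were recovered, 3.8% of calls were unchanged genes, and the list test recovered 100% of the lists shifted by 0.3 and called 0% of the unshifted lists. The simulated genes were independent of each other, which real genes are not. Only 200 genes were changed in the gene test, none of them low in parental cells, whereas 9448 passed in the real data. The shares of genes recovered therefore do not speak for low genes or for a comparison in which most genes change. In the list test, too, most genes outside the shifted lists were unchanged. Its shares thus do not speak for a list set against genes that mostly change. In the real data the heat shock and proteasome list, with a mean of -0.37, did not pass (camera adjusted p = 0.1408).

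Of the named genes, 20 overlap another gene with at least 1 FPKM in some library, 6 of them on the same strand. For these, for the HLA, keratin, AKR1C and ribosomal protein genes, which have close paralogs or pseudogenes, and for the chemokine genes of the CXCL family, reads may have been divided between copies, and their values carry that uncertainty. Alternatives covered the pseudocount, filters on low values, scaling, TPM, the replicate number as a block, each library left out, and other set tests. Figures and the checks of the closing section used Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and Matplotlib 3.10.9.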

Results

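The data comprised 6 RNA-seq libraries of H1975, an EGFR-mutant human lung adenocarcinoma line, 3 from parental cells and 3 from cells made resistant to the EGFR inhibitor osimertinib and cultured with 1 µM of it. The estimated mapped sequence was 14.7, 10.8 and 11.1 gigabases in parental replicates 1 to 3 and 10.6, 9.72 and 11.5 gigabases in resistant replicates 1 to 3. Between 11410 and 11555 genes of the series table reached 1 FPKM in a library. Mitochondrially encoded mRNA took 8.07%, 8.91% and 10.0% of TPM in the parental libraries and 11.2%, 9.48% and 10.0% in the resistant ones. Rank correlations over the 12107 tested genes were 0.9947 to 0.9962 between libraries of one group and 0.8456 to 0.8538 between groups. The first principal component of the 500 most variable genes held 98.0% of their variance and separated the groups. These genes were chosen by variance over all 6 libraries, which favours genes that differ between groups.

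The comparison of resistant with parental cells asked which genes differed in expression after resistance to osimertinib had developed. Among the largest decreases were those of epithelial genes. EPCAM, an epithelial adhesion molecule (2:47572297-47614740), fell from 211 ± 15.6 FPKM to 1.02 ± 0.237 (SD, n = 3 per group). CDH1, E-cadherin (16:68771128-68869451), fell from 68.6 ± 3.72 to 0.0248 ± 0.0135 FPKM, and its neighbour CDH3, P-cadherin (16:68670092-68756519), from 130 ± 2.13 to 0.554 ± 0.0410. The largest increases were those of COL12A1, a fibril-associated collagen (6:75794042-75915767), from 0.268 ± 0.0735 to 94.5 ± 9.17 FPKM, and CCL2, a monocyte chemoattractant (17:32582304-32584222), from 2.78 ± 0.506 to 182 ± 7.95 FPKM. The intermediate filament gene VIM (10:17270258-17279592) rose from 124 ± 11.8 to 685 ± 43.6 FPKM, and the calcium-binding protein gene S100A4 (1:153516089-153522612) from 6.78 ± 0.897 to 267 ± 23.4 FPKM.

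In all, 9448 of the 12107 tested genes passed an FDR of 0.05, 4833 higher and 4615 lower in resistant cells. The p-values rest on the spread among libraries of the parental line and its only derivative here, not among resistant lines. Of these, 2342 also differed by at least 1 on the log2 scale, 1205 higher and 1137 lower. At an unadjusted p under 0.05 there were 9598 genes. A change of at least 3 on the log2 scale was seen for 203 genes. The 3 resistant libraries lay entirely above or below the 3 parental ones for 79.8% of tested genes, against 10% by chance. In each of the 92 named genes the groups did not overlap, and each named gene kept its direction and its call under every alternative in which it was tested. Apart from genes fixed in advance, such as EGFR, the rule chose them by size of change or adjusted p in these same data. Their stability was thus largely set by the choice. When only genes at 1 FPKM or more in both groups were tested, 1551 genes passed both thresholds.

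The other genes with the largest increases by the fixed rule were QPRT, an enzyme of NAD synthesis (16:29674600-29710020, log2 fold change 5.35 ± 0.0751 SE, adjusted p = 3.7e-14), ANKRD1, a target of the YAP coactivator (10:92671853-92681033, 5.14 ± 0.0706, adjusted p = 3.3e-14), BAMBI, a decoy receptor of TGF-beta signalling (10:28966271-28971868, 4.97 ± 0.0979, adjusted p = 3.2e-12), and KRT17, a keratin of basal epithelia (17:39775689-39781094, 4.91 ± 0.153, adjusted p = 2.6e-08). The other largest decreases were those of KRT19, a keratin of simple epithelia (17:39679869-39684560, -6.69 ± 0.114, adjusted p = 2.5e-11), SPINT2, a serine protease inhibitor (19:38734675-38783254, -5.86 ± 0.0734, adjusted p = 1.6e-14), LAD1, ladinin (1:201342372-201368736, -5.64 ± 0.0611, adjusted p = 6.1e-15), and ESRP1, a splicing regulator of epithelial cells (8:95653302-95719694, -5.64 ± 0.0603, adjusted p = 6.1e-15).

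**Figure D1:**
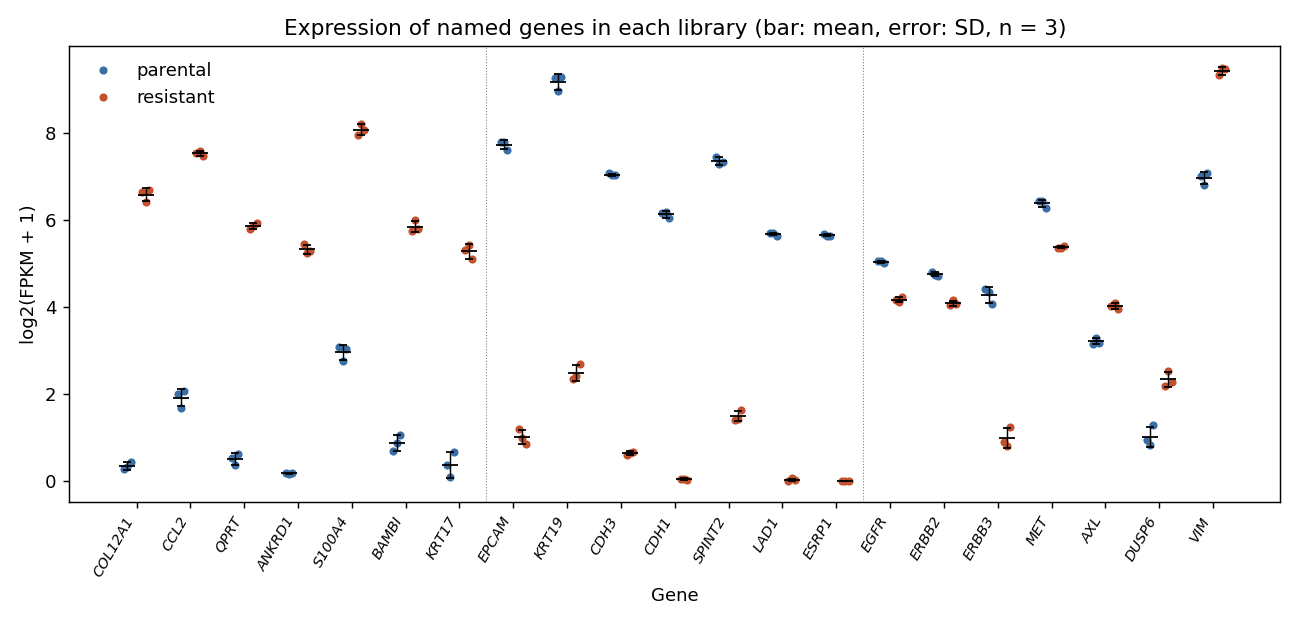
Expression of the named genes in each library as log2(FPKM + 1) on the vertical axis, with parental libraries in blue, resistant libraries in orange, bars for the mean and error bars for the SD (n = 3 per group). From left to right are the 7 largest increases, the 7 largest decreases and the genes fixed in advance; CDH1 and ESRP1 lie near 0 in all resistant libraries, and VIM, already at 124 FPKM in parental cells, is higher in each resistant library.

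All 20 tested members of the epithelial adhesion list fell, 17 of them by at least 1 on the log2 scale, with a median of -3.50 (camera adjusted p = 4.2e-10). With an estimated correlation the adjusted p = 0.3168. The desmosomal gene DSP (6:7541808-7586950) fell from 45.2 ± 0.893 to 0.0148 ± 0.00768 FPKM. Not all keratins were lost: KRT8 fell by 0.40 and KRT18 by 0.65 on the log2 scale and stayed at 384 and 274 FPKM, values named after they were seen. Of 13 tested mesenchymal markers 9 rose and 3 fell, and the list did not pass (camera adjusted p = 0.0855). ZEB1, a repressor of epithelial genes (10:31607424-31818742), rose from 0.214 ± 0.0922 to 26.2 ± 3.17 FPKM. Members chosen after their values were seen moved apart: ZEB2 rose from 0.00538 to 7.85 FPKM, while the fibronectin gene FN1 fell from 95.7 to 8.97 and SNAI1 from 22.8 to 3.23 FPKM. CDH2, N-cadherin, also chosen afterwards, was at 0.0672 and 0.0768 FPKM, below the level tested. Among 6 squamous and basal markers 2 rose and 4 fell (camera adjusted p = 0.4813), with KRT17 higher and the serpin gene SERPINB5 (18:61143994-61172318) lower at 18.8 ± 0.603 and 0.137 ± 0.0173 FPKM.

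Of 5 tested markers of lung differentiation 1 rose and 3 fell (camera adjusted p = 0.3749). The lung lineage factor NKX2-1, named after its values were seen, was at 27.9, 28.7 and 23.6 FPKM in parental replicates 1 to 3 and listed at 0 in each resistant library. FOXA2, likewise chosen afterwards, was at 4.05, 4.22 and 3.64 FPKM in the parental libraries and listed at 0 in the resistant ones, and ABCA3 rose from 3.44 to 41.6 FPKM. Markers of other cell types gave a mixed picture. Of 5 tested fibroblast markers 4 rose and 1 fell (camera adjusted p = 0.05197, and under 0.05 in several alternatives), with PDGFRB (5:149493400-149535435) at 0.0444 ± 0.0149 and 3.94 ± 0.445 FPKM and COL1A1 (17:48260650-48278993) at 2.45 ± 0.249 and 15.8 ± 1.89 FPKM, while COL3A1, DCN and LUM, chosen after their values were seen, were each under 1 FPKM in both groups. Too few members of 4 lists were tested for a set test. Of 3 leukocyte markers 2 rose, CD14 and CD68, and of 2 endothelial markers CDH5 rose and EGFL7 fell. Of 2 neuroendocrine markers ENO2 rose, and of 2 cancer-testis antigens XAGE1B and PRAME both rose. All of these were named after their values were seen.

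EGFR (7:55086714-55324313), the target of the drug, fell from 31.7 ± 0.472 to 16.9 ± 0.732 FPKM, and its partners ERBB2 (17:37844167-37886679) from 25.8 ± 0.888 to 15.9 ± 0.725 and ERBB3 (12:56473641-56497289) from 18.3 ± 2.39 to 0.984 ± 0.324 FPKM. The EGFR ligand genes TGFA (2:70674412-70781325, log2 fold change -2.97 ± 0.0772 SE, adjusted p = 4.6e-12) and AREG (4:75310851-75320726, -1.80 ± 0.0672, adjusted p = 1.3e-10) fell as well. Of 8 tested members of the EGFR family and ligand list 2 rose and 6 fell (camera adjusted p = 0.05197, and under 0.05 in several alternatives). The 2 that rose, named after their values were seen, were also ligand genes. HBEGF rose from 1.71 ± 0.341 to 10.4 ± 1.21 FPKM, and NRG1 from 9.43 ± 0.357 to 11.9 ± 2.34 FPKM. Of 17 genes of ERK output, which follow the activity of the kinase cascade below EGFR, 10 rose and 4 fell (camera adjusted p = 0.307). The ERK phosphatase gene DUSP6 (12:89741009-89747048) rose from 1.03 ± 0.343 to 4.04 ± 0.624 FPKM and the transcription factor gene ETV1 (7:13930853-14031050) from 0.793 ± 0.118 to 8.01 ± 0.464, while FOSL1 (11:65659520-65668044), a member of the AP-1 family, fell from 96.1 ± 2.10 to 28.4 ± 2.57 FPKM. Among 13 tested receptor tyrosine kinases that can bypass EGFR, 8 rose and 5 fell (camera adjusted p = 0.4813). PDGFRB, given above among the fibroblast markers, had the largest rise of this list (log2 fold change 2.24). MET (7:116312444-116438440) fell from 81.9 ± 5.01 to 40.2 ± 0.624 FPKM and MST1R (3:49924435-49941299) from 13.6 ± 0.701 to 3.52 ± 0.216, whereas AXL (19:41725108-41767671) rose from 8.22 ± 0.466 to 15.1 ± 0.731 FPKM. Of 13 bypass ligands and IGF regulators 6 rose, with IGFBP7 among them (log2 fold change 2.21), and 6 fell, FGF13 among them (-2.29), and the list did not pass (camera adjusted p = 0.8584).

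Of 22 mitotic genes 20 fell and 0 rose, with a median of -0.51 (camera adjusted p = 0.00025), and of 22 genes of the G1/S transition and DNA replication 15 fell and 2 rose, with a median of -0.48 (camera adjusted p = 0.017). With an estimated correlation the adjusted p = 0.8454 for both. The ubiquitin-conjugating enzyme gene UBE2C (20:44441215-44445596) fell from 210 ± 4.30 to 72.6 ± 3.81 FPKM, and the topoisomerase gene TOP2A (log2 fold change -1.28), the mitotic kinase gene AURKA (-1.34), the ribonucleotide reductase gene RRM2 (-1.25) and the replicative helicase genes MCM7 (-1.16) and MCM4 (-1.18) were each lower by more than 1 on the log2 scale. The p53 targets were split, with 7 higher and 7 lower of 22, a median of 0.02, a mean of -0.07 and a downward set test (camera adjusted p = 0.8813). By at least 1 on the log2 scale, 3 of the p53 targets rose and 2 fell. The 2 that fell were those with the lowest adjusted p. CDKN1A, the p21 inhibitor of cyclin-dependent kinases (6:36644305-36655116), fell from 21.8 ± 1.07 to 5.08 ± 0.906 FPKM and PHLDA3 (1:201434620-201438365) fell by 3.93 on the log2 scale.

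In the cholesterol synthesis list 15 of 22 fell and 5 rose, with a median of -0.95 (camera adjusted p = 0.017). NSDHL (X:151999511-152038273) fell from 46.8 ± 0.715 to 16.1 ± 0.886 FPKM, MSMO1 by 1.40 and CYP51A1 by 1.27 on the log2 scale. In the list of hypoxia and glycolysis 17 of 25 fell and 5 rose, with a median of -0.59 (camera adjusted p = 0.026). By at least 1 on the log2 scale, 3 of this list rose and 2 fell, and its mean was -0.28. The declines with the lowest adjusted p were those of PDK1 (log2 fold change -1.30), PFKFB4 (-1.34) and BNIP3 (-0.97). Of 27 nuclear genes of oxidative phosphorylation 19 fell and 3 rose, with a median of -0.27 (camera adjusted p = 0.017), led by UQCRB (-1.29), COX6C (-1.23) and NDUFA4 (-0.90). Only 2 of them, UQCRB and COX6C, fell by at least 1 on the log2 scale, and 0 rose by as much. UQCRB (8:97238148-97247862) and COX6C (8:100885428-100906290) lie near each other on chromosome 8, and NDUFA4 is on chromosome 7. Chromosomes 7 and 8 are among those given below as lower in resistant cells. With an estimated correlation the adjusted p = 0.8454 for each of these 3 lists. The mitochondrially encoded mRNAs did not move with them: of 13, 7 rose and 1 fell (camera adjusted p = 0.3108), with MT-CYB at 1847 and 2996 FPKM. Of 14 fatty acid synthesis genes 5 rose and 7 fell (camera adjusted p = 0.551), and the desaturase gene SCD (-1.60) and the synthase gene FASN (-1.50) fell.

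Of 23 genes of the integrated stress response and amino acid supply 18 rose and 3 fell, with a median of 0.76 (camera adjusted p = 0.0061). The stress-induced gene NUPR1 (16:28548606-28550495) rose from 1.54 ± 0.245 to 44.6 ± 5.40 FPKM, STC2 by 2.43 and the transcription factor gene ATF3 by 2.09 on the log2 scale. Of 19 genes on the endoplasmic reticulum chaperone list, not all of which encode chaperones, 13 rose and 2 fell, with a median of 0.51 (camera adjusted p = 0.017). The transcription factor gene XBP1 was at 33.9 ± 3.21 and 166 ± 10.5 FPKM. HERPUD1, also not a chaperone gene, had a log2 fold change of 2.13 and the chaperone gene HYOU1 one of 1.46. Genes of protein folding, named after their values were seen, moved less: CALR (0.79) and HSPA5 (0.68) rose, HSP90B1 (0.10) did not pass and PDIA4 (-0.50) fell. Of 22 NF-kB and cytokine genes 18 rose and 1 fell, 16 by at least 1 on the log2 scale, with a median of 2.34 (camera adjusted p = 2.9e-05). Beside CCL2, the neutrophil chemokine gene CXCL5 (4:74861359-74864496) rose from 0.708 ± 0.149 to 22.6 ± 1.01 FPKM and the superoxide dismutase gene SOD2 (6:160090089-160183561) from 121 ± 6.15 to 790 ± 63.9. With an estimated correlation the adjusted p = 0.8454 for each of these 3 lists. Of 20 YAP and TEAD targets 14 rose and 4 fell, with a median of 0.76 (camera adjusted p = 0.013, adjusted p = 0.6005 with an estimated correlation), with the matricellular gene CYR61 (1:86046444-86049645) at 28.5 ± 1.81 and 241 ± 22.5 FPKM and DLC1 (8:12940870-13373167), a GTPase-activating protein of RhoA, at 0.267 ± 0.0352 and 10.8 ± 0.643.

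Of 25 interferon response genes, 16 fell and 5 rose, with a median of -0.53 (camera adjusted p = 0.041, adjusted p = 0.8454 with an estimated correlation). This call also ended without parental replicate 3 (adjusted p = 0.0948), without resistant replicate 2 (adjusted p = 0.0596) and with median-of-ratios scaling, an alternative chosen after the data were seen (adjusted p = 0.0633). CMPK2 (log2 fold change -1.71), the neighbouring antiviral gene RSAD2 (-1.01) and ISG15 (-0.95) had the lowest adjusted p among the members that fell, and BST2, named after its values were seen, rose from 106 to 411 FPKM. Antigen presentation genes did not pass (camera adjusted p = 0.1177), although all 18 tested members passed the gene test, 13 higher and 5 lower. The class II gene HLA-DRA (6:32407619-32412823) fell from 5.47 ± 0.629 to 0.0113 ± 0.0195.

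The remaining lists did not pass the set test. NRF2 targets counted 5 higher and 14 lower of 21 (camera adjusted p = 0.0855), with HMOX1 (-3.07), heme oxygenase, and AKR1C3 (4.78), an aldo-keto reductase, moving apart. NOTCH pathway genes counted 2 higher and 7 lower of 11 (camera adjusted p = 0.0855), with JAG2 (-2.49) and HES1 (-2.04) lower. Lysosome and autophagy genes counted 14 higher and 5 lower of 24 (camera adjusted p = 0.06796), with TPP1 (1.91) and TFEB (2.13) higher. Extracellular matrix and integrin genes counted 9 higher and 13 lower of 22 (camera adjusted p = 0.4813), with a median of -0.60, a mean of -0.06 and an upward direction in fry, and the integrin subunit gene ITGB1 (10:33189247-33294720) rose from 116 ± 3.57 to 712 ± 21.8 FPKM. TGF-beta targets counted 7 higher and 8 lower of 18 (camera adjusted p = 0.7309), with BAMBI higher and PMEPA1 (-3.21) lower. Apoptosis regulators counted 8 higher and 4 lower of 19 (camera adjusted p = 0.4813), with BIRC3 (2.26) and BCL2 (1.52) higher. Cytosolic ribosomal protein genes counted 6 higher and 17 lower of 33 (camera adjusted p = 0.1408), with RPL7 (-1.29) and RPS6 (-1.14) lower.

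Heat shock and proteasome genes counted 4 higher and 10 lower of 20 (camera adjusted p = 0.1408), with HSP90AA1 (-1.86) lower and CRYAB listed at 0 in the parental libraries and at 2.64, 2.06 and 2.17 FPKM in resistant replicates 1 to 3. Drug efflux transporters counted 2 higher and 3 lower of 6 (camera adjusted p = 0.8015), with ABCC10 (1.08) higher and ABCG2 (-1.65), the breast cancer resistance protein, lower. ABCB1, chosen after its values were seen, was listed at 0 in both groups. Aryl hydrocarbon receptor and drug-metabolising genes counted 4 higher and 4 lower of 10 (camera adjusted p = 0.7025), with a median of 0.08, a mean of -0.31, CYP1A1 (2.08) higher and CYP24A1 (-3.81) lower. WNT genes counted 4 higher and 4 lower of 8 (camera adjusted p = 0.9605), with a median of 0.02, a mean of -0.15, WNT5A (1.33) higher and WNT7B (-2.83) lower. Ferroptosis and glutathione genes counted 8 higher and 6 lower of 14 (camera adjusted p = 0.8584), with a median of 0.23 and a mean of -0.04. In this list CHAC1 (1.69) was higher and HMOX1 (-3.07), also an NRF2 target, was lower. Stem-like and tolerance markers counted 3 higher and 3 lower of 6 (camera adjusted p = 0.8015), with ALDH1A3 (-2.77) and NES (-0.61) lower.

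**Figure D2:**
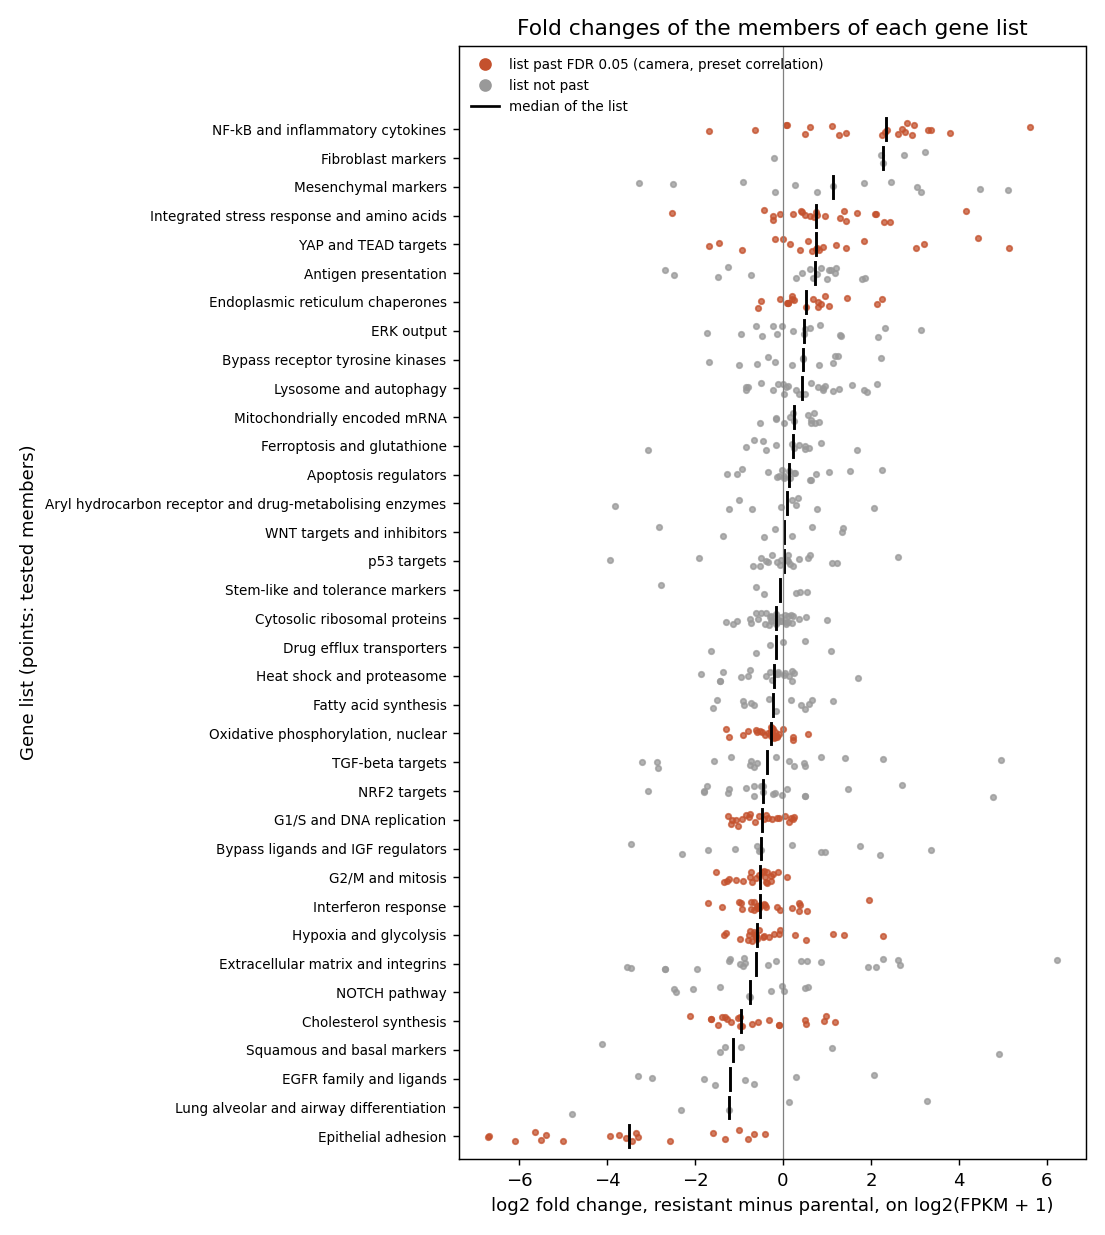
Log2 fold changes, resistant minus parental, of the tested members of the 36 gene lists with a set test. Each point is a gene, black bars are list medians, and orange marks the 11 lists past an FDR of 0.05 with the preset correlation; the epithelial adhesion list lies lowest, with a median of -3.50, and the NF-kB list highest, with a median of 2.34.

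Adjusted over the list alone, the number of members past 0.05 was as over all genes in 37 of the 40 lists, and was 14 in place of 12 for fatty acid synthesis, 3 in place of 2 for leukocyte markers and 6 in place of 8 for mitochondrially encoded mRNA. In all, 11 lists passed camera with the preset correlation, 4 higher and 7 lower, 0 passed with an estimated correlation and 30 passed fry, which asks only whether a list's genes move one way on balance.

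Neighbouring genes also moved together. Of the 23 chromosomes tested, 8 passed camera with the preset correlation, chromosomes 5, 6 and 11 higher and 2, 7, 8, 9 and 13 lower in resistant cells. On chromosome 7, which carries EGFR and MET, 22.5% of 568 tested genes were higher and the median log2 fold change was -0.55 (camera adjusted p = 1.5e-09). On chromosome 11, 74.4% of 695 genes were higher, with a median of 0.37 (camera adjusted p = 1.3e-05). With an estimated correlation 0 chromosomes passed (adjusted p from 0.9415 to 0.9554), and chromosome 8 did not pass without the filter on low FPKM (adjusted p = 0.0971). Chromosome 10 as a whole did not pass (camera adjusted p = 0.2857), but a segment of it, found after the data were seen by a scan of 20 neighbouring genes at a time, stood apart. Between THNSL1 and ZNF37A (10:25305587-38414472), all 34 tested genes were higher in resistant cells and 32 by at least 1 on the log2 scale, with a median of 2.06, against 0.01 for the 436 tested genes of the chromosome outside. The segment holds ZEB1, BAMBI and ITGB1, and also genes chosen after their values were seen, such as YME1L1, a mitochondrial protease gene, at 50.1 and 279 FPKM, RAB18 with a log2 fold change of 3.01 and KIF5B at 25.4 and 92.8 FPKM.

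**Figure D3:**
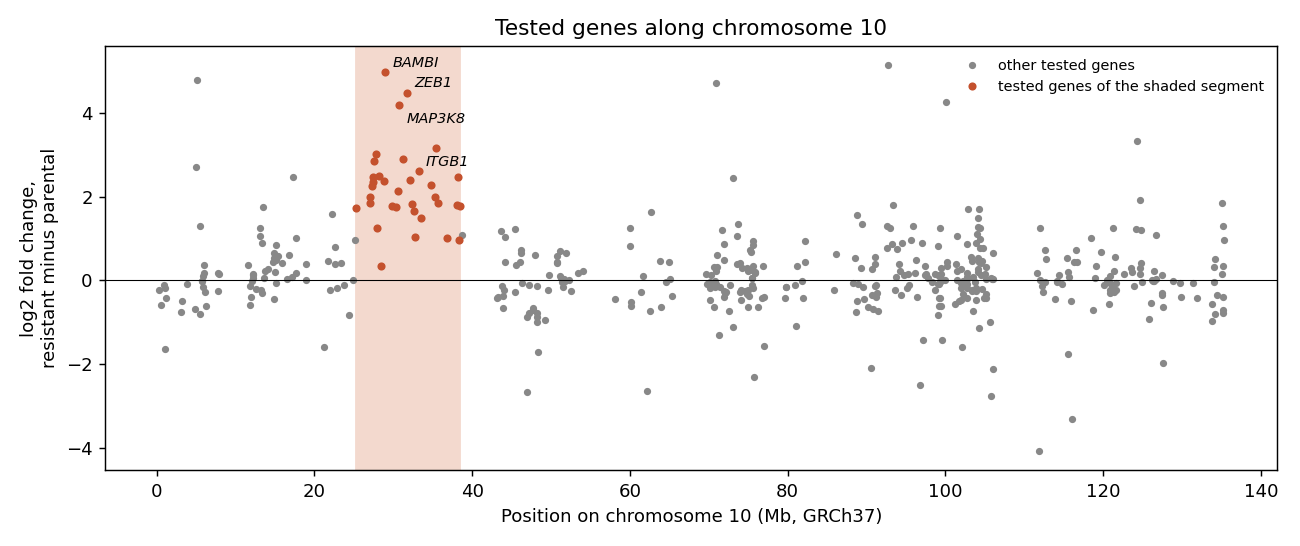
Log2 fold change, resistant minus parental, of each tested gene against its position on chromosome 10 in megabases (GRCh37). The shaded segment holds 34 tested genes, drawn in orange, with a median of 2.06, and the grey genes outside it have a median of 0.01.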

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

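The tests in this part were chosen after the results were seen. Signals appeared in gene IDs of the library files that the comparisons above do not use. Of 996 long noncoding RNA genes tested outside the series table, 204 passed both thresholds (FDR of 0.05 and a log2 fold change of at least 1), 133 higher and 71 lower in resistant cells. The genes XIST and TSIX and clone names were set aside before the genes below were picked. By the same limits of level and overlap as for the named genes, the 4 highest were LINC01021, at 0.425 ± 0.0701 FPKM in parental and 27.5 ± 2.62 FPKM in resistant cells (SD, n = 3), MIR146A, the host transcript of an NF-kB-induced microRNA, at 0.0203 ± 0.0133 and 9.36 ± 1.32, LINC00882 at 0.248 ± 0.0770 and 10.8 ± 2.11, and WAC-AS1, which lies in the raised segment of chromosome 10, at 6.34 ± 0.152 and 42.1 ± 1.77 FPKM. Among those that fell were UCA1, from 214.5 ± 4.29 to 11.5 ± 3.21 FPKM, and LINC00511, which fell by 2.93 on the log2 scale.

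The first pattern weighed is the fall of epithelial genes, many to near 0, with a rank correlation between groups of at most 0.854. Fibroblasts in the resistant cultures are argued against by their abundant transcripts. With CDH1 at 0.0248 FPKM such cells would have to make up nearly the whole culture. Yet the highest mean among COL1A2, COL3A1, DCN and LUM, picked after their values were seen, was 0.530 FPKM in the resistant cells. Of the other fibroblast markers, PDGFRB, COL1A1, C1S and C1R rose and FBLN1 fell. PDGFRA, FAP, PDPN and MFAP5 were each under 1 FPKM in both groups. Of the 13 fibroblast markers, 5 stand on another list too. A culture of another cell line under the resistant label stays open, since expression alone holds no genotype. The longest run of neighbouring expressed genes that were off in parental and on in resistant cells was 2, which decides nothing. A stable change of state of the resistant cells, and an effect of the drug in the medium, also stay open and were not tested apart.

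The second pattern is the segment of chromosome 10. The highest median over 20 neighbouring genes was 2.38, against 1.22 on chromosome 19, the next highest, and at most 1.13 in 1000 shuffled gene orders, so separate changes of single genes would not give it. The highest windows of chromosomes 19 and 6 (1.17 on chromosome 6) also exceeded the shuffled orders, by less. Falling windows, down to -1.45 on chromosome 14, were not compared with shuffled orders. Scaling of the libraries is argued against by the median of 0.01 outside the segment and 0.13 in the 40 genes that flank it. More copies of the segment in the resistant cells may be the source, as 100% of its tested genes were higher, and the 20 genes with at least 5 FPKM in both groups had a median ratio of means of 4.197, but unevenly, from 1.28 for MPP7 to 10.1 for CREM. The borders were drawn on the same fold changes and DNA was not analysed here, so this share decides nothing and added copies remain a hypothesis; a regional change of transcription with no added copies, or another cell line with its own copy numbers, stays open.

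The third pattern is a set of 25 genes whose 3 replicates of a group spanned at least 4-fold on the log2(FPKM + 1) scale, such as RPS10-NUDT3, at 7.69 FPKM in parental replicate 2 and listed at 0 in the other parental libraries, and TOMM6, at 9.93, 4.58 and 0.677 FPKM in the resistant libraries. Of these, 92% overlap another gene on the same strand, against 33.4% of the other 12082 tested genes (two-sided Fisher's exact test, p = 1.6e-09). Summing the overlapping genes left a median log2 spread of 0.218, but adding their mean level to every library left 0.194 (23 genes, 11 lower after summing, two-sided exact Wilcoxon signed-rank test, p = 0.665), so whether reads were divided among overlapping gene models stays open. A single odd library is argued against, since none deviated most in more than 28% of the genes. Of the 25 genes, 3 passed both thresholds between groups.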

How the results depend on the processing

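The 6 alternatives of scaling, TPM, stricter filters and all gene IDs, and for lists and chromosomes the pseudocount and the filter, were chosen after the data were seen. Under the 15 alternatives run, the count of genes past an FDR of 0.05 ranged from 7295 to 11014 beside 9448, and from 8985 to 9261 with 1 library left out. The count past both thresholds ranged from 2310 to 2386 with 1 library left out. It rose from 2342 to 2980 with a pseudocount of 0.1 (1566 higher, 1414 lower). It fell to 1551 when genes had to reach 1 FPKM in both groups, which leaves out the genes lost or gained entirely. Gene lists past camera numbered 10 to 13 with 1 library left out, 0 with an estimated inter-gene correlation and 30 with fry, and chromosomes numbered 8 in each left-out fit and 0 with an estimated correlation. The cause was not tested. The share of higher genes among those past both thresholds was 51.5%, and 50.6% to 56.8% under the scalings. The scaling that moved the median of all genes most, to the sum of nuclear genes, put it at 0.0807. All 1336 values of named genes under alternatives kept their direction and call. Most of these genes had been chosen by their change or adjusted p in the same data, which favours this. Leaving aside the estimated correlation and fry, 3 list calls were lost, all of the interferon list, and 22 were gained.

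Replicate numbers did not pair the samples: same-numbered deviations correlated at -0.135, 0.076 and 0.099, and not every sample correlated best with its own number. With the replicate block 2337 genes passed both thresholds, 12 lists and 8 chromosomes passed. Tests that need counts were not run: DESeq2's size factors, library size alone, filters on counts, the DESeq2 Wald test and limma-voom. The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split but the real one mixes the groups, so the group difference adds to its within-group spread. Few or no gene calls were thus fixed in advance for these splits. They also keep part of the real difference, so their list and chromosome counts give no chance level. The real split gave 9448 genes and the highest other 0, 2342 and 0 genes past both thresholds (1 split of 10 in each case), 11 lists and the highest other 15 (4 splits, the real one included, gave at least 11), and 8 chromosomes and the highest other 8 (3 splits, the real one included). Depth in reads is unknown, so precision at low FPKM rests on the spread of 3 libraries.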

Other observations

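The tests and genes in this part were chosen after the data were seen. Some genes were switched between the groups, with chromosome Y and XIST left out of the counts. Below 0.1 FPKM on average in parental and at 5 FPKM or more in resistant cells were 35 genes, and 55 were the reverse. The 55 include LUC7L2, at 5.265, 1.29 and 10.1 FPKM in parental replicates 1 to 3. It is among the 25 genes with a 4-fold spread between replicates. Among the first were LTF, lactotransferrin, at 0.00228 and 26.7 FPKM, BDKRB1, an inducible bradykinin receptor gene, at 0.0549 and 30.6 FPKM, TMPRSS15, the gene of the intestinal protease enteropeptidase, at 0.000866 and 16.9 FPKM, CDH11, a cadherin of mesenchymal cells, at 0.00282 and 5.58 FPKM, and SERPINB2 at 0.0499 and 27.1 FPKM. The olfactory receptor gene OR2T8 (1:248084320-248085258) was listed at 0 in the parental libraries and at 27.4, 25.1 and 26.5 FPKM in resistant replicates 1 to 3. Among genes that were off in resistant cells were SFTA3 (14:36942493-36983034), at 16.0, 17.0 and 12.8 FPKM in parental replicates 1 to 3 and listed at 0 in resistant ones, which neighbours NKX2-1, and the epithelial transcription factor gene GRHL2 at 14.5 and 0.00537 FPKM.

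Antigen presentation genes moved both ways. HLA-B, HLA-C, HLA-E, HLA-F and B2M were higher in resistant cells, HLA-B at 138 and 486 FPKM, whereas the class II genes HLA-DRA and HLA-DPA1, the invariant chain gene CD74 at 43.5 and 6.98 FPKM and the class II regulator CIITA at 3.15 and 0.755 FPKM were lower. The class II gene HLA-DMA was an exception, with a log2 fold change of 0.29. Within the ERK output list, MYC was at 76.5 and 349 FPKM and IER3 at 28.3 and 257 FPKM, both higher, and FOSL1 was lower.

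Each list past the set test was set beside its neighbourhood, with no test of the difference. Of the falling lists, the members of the epithelial adhesion list had a mean log2 fold change of -3.53, against a mean of -0.20 for the medians of the 20 tested genes nearest each member. The means and those of the neighbours were -0.49 and -0.08 for G1/S, -0.63 and 0.03 for mitotic genes, -0.62 and 0.09 for cholesterol synthesis, -0.28 and 0.07 for hypoxia, -0.33 and -0.05 for oxidative phosphorylation and -0.37 and -0.09 for interferon response. Of the rising lists, they were 0.90 and -0.10 for the integrated stress response, 0.60 and 0.00 for the endoplasmic reticulum chaperone list, 1.94 and 0.05 for NF-kB genes and 1.05 and 0.10 for YAP targets.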
